A study of Mus musculus with 40 samples.

How the data were processed

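The authors deposited RSEM expected counts for 42037 gene symbols in 40 libraries, and TPM (length-scaled transcript share) values that the authors computed with RSEM for the same symbols and libraries. Per the submitters' processing notes, STAR 2.7.10a and RSEM 1.3.3 were used with genome build GRCm38.p4. The gene annotation is not given in the sources used here. Per the labels' protocols, total RNA came from 1 whole retina per sample, cDNA was made with SMART-Seq mRNA and libraries with Nextera XT. Neither strand nor molecular identifiers are mentioned there, so reads of 1 gene cannot be taken as independent molecules. Of the nonzero expected counts, 15.7% were not whole, and all were rounded before fitting. The table holds 2036 symbols with a suffix that marks a further copy of a symbol, of which 516 were tested. Coordinates of genes named in the text come from the GENCODE annotation of GRCm38 and were matched by symbol.

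Counts were scaled with TMM factors and fitted with edgeR's quasi-likelihood model (robust), using all 40 libraries and 10 groups. Low counts were removed with edgeR's filter by group, which left 23495 genes. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 within its comparison. There were 19 comparisons, of which 8 were treated as primary: OIR with control IgG against control retinas, and each of the 3 antibodies against IgG, at each age. CPM values in the text are means over the 4 retinas of a group with the SD, and folds are the model's. The adjusted p-values of edgeR measure the spread between retinas, which were treated as independent, since the labels do not say which retinas came from 1 mouse or litter.

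In addition, 36 gene lists were tested in each comparison with camera (limma, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 36 lists. Each was also tested with camera's estimated correlation and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. The number of list members called was counted with p adjusted over all genes and adjusted over the list alone. The lists covered vessels (endothelial, tip cell and neovascular endothelium, blood-retina barrier endothelium, Norrin and Wnt signalling, VEGF and angiopoietin ligands and receptors, pericyte and smooth muscle), hypoxia, matrix, inflammation and blood cells, glia, the neuron classes of the retina, pigment epithelium, lens and crystallins, and metabolism and stress. Genes can stand in more than 1 list.

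Genes to be named were set by a rule. In the 8 primary comparisons it took the 8 called genes per direction with the largest fold, with a mean of at least 5 CPM in the higher group and all 4 libraries of that group above all 4 of the other, gene models without a proper symbol excluded. It added up to 4 called members of each list that passed its test or held at least 3 called members. It also always took Vegfa, Angpt2, Kdr, Flt1, Tek, Esm1, Apln, Plvap, Pecam1, Gfap, Aif1 and Ccl2. In the other comparisons it took the 5 called genes per direction with the smallest p, and where no gene was called the 3 genes with the smallest p. The groups, comparisons, lists, naming rule and most alternative settings were chosen before the data were examined. Covariates for pigment epithelium and lens RNA, Y-linked counts and mitochondrial share, and counts without 5 libraries in doubt, were chosen after seeing the data.

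DESeq2 was run as an alternative model, as were limma-voom with sample quality weights, limma-trend on log2(TPM + 1), RLE factors, no filter and a fit to the compared groups alone. The edgeR step was tested on simulated counts of the 23495 genes with known changes. For the OIR comparison at P17 it found 5.97% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 80.3% of those changed 4-fold, with 2.2% false calls. For the anti-ANG2 comparison at P19 the shares were 22.4%, 43.3% and 81.8%, with 1.94% false calls. Changed genes were drawn only among genes above a minimum mean count. The counts came from the real means, dispersions and library sizes, so the shares do not cover structure that crosses the groups. In the real libraries of the anti-ANG2 comparison at P19 a regrouping called 656 genes, so the false-call shares hold for the simulated counts only.

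All antibody groups at an age share the same IgG libraries. To compare antibody effects with OIR effects, the 4 IgG libraries were therefore divided 2 and 2 in both roles, in all 6 ways: OIR genes were called with 2 of them, and antibody effects were measured against the other 2. Simulated counts with no antibody effect gave the values that shared controls alone produce.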

Results

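RNA-seq was done on 40 whole retinas of C57BL/6J mice, in 10 groups of 4 retinas, at postnatal days 17 (P17) and 19 (P19). At each age, 1 group came from control mice (nOIR) and 4 groups came from mice with oxygen-induced retinopathy (OIR), in which pups breathe 75% oxygen from P7 to P12 and return to room air, so that the retina loses vessels and then grows abnormal ones. The eyes of OIR mice received 1 µl of antibody at P14: anti-ANG2 (clone LC10) or anti-VEGFA (clone B20.4.1), both at 0.2 µg/µl, or a bispecific antibody to VEGFA and ANG2 or control IgG, both at 0.4 µg/µl. The labels do not say whether control mice were injected, so the OIR comparisons contain any effect of injection and IgG. Total expected counts ran from 9160000 to 25800000 per library (mean 17100000, SD 3520000, n = 40). By Xist and Y-linked counts, the sexes were not balanced: all 4 IgG retinas at P19 and all 4 anti-VEGFA retinas at P17 carried Y-linked counts, whereas all 4 bispecific retinas at P19 and all 4 anti-ANG2 retinas at P17 carried Xist and almost none.

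The first comparison, OIR with IgG against control retinas at P17, shows the disease state in which the antibodies were tested. Genes of the response to low oxygen rose in OIR. Ndufa4l2, a HIF-induced mitochondrial protein that is also a pericyte marker, rose 10.9-fold (80.3 ± 12 against 7.32 ± 1.41 CPM, SD, n = 4 each, adjusted p = 1.1e-11). Adm, which encodes the vasodilator adrenomedullin, rose 20.7-fold (31.8 ± 7.82 against 1.54 ± 0.834 CPM, adjusted p = 6.9e-08). Vegfa (GRCm38 chromosome 17, 46016993 to 46032369) rose 2.35-fold, from 97.1 ± 6.89 to 228 ± 23.9 CPM (adjusted p = 0.00016), a call that limma-trend on TPM did not make (adjusted p = 0.12). Of 30 measured hypoxia and HIF targets, 12 were called higher and 0 lower (21 higher adjusted over the list alone), with a median log2 change of 0.69 (camera adjusted p = 1.4e-17, and adjusted p = 0.002 with an estimated correlation). They included Bnip3, a mitophagy receptor (2.5-fold), and Slc16a3, a lactate exporter (2.46-fold). Glycolysis rose as a group, with 7 of 18 genes called (13 adjusted over the list alone) and a median log2 change of 0.51 (adjusted p = 1.3e-12, and adjusted p = 0.031 with an estimated correlation). Its called members included Pgk1 (1.68-fold), Tpi1 (1.75-fold) and Ldha (1.69-fold). With pigment epithelium and lens RNA as covariates 2 of the 18 were called, and Tpi1 and Ldha missed the threshold (adjusted p = 0.054 and adjusted p = 0.076).

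Genes of growing vessels and mural cells were also higher at P17. Apln, the apelin peptide of endothelial tip cells, rose 12.2-fold (50.6 ± 8.2 against 4.09 ± 1.52 CPM, adjusted p = 8.3e-09). It stands in the tip cell and neovascular list, which rose with a median log2 change of 0.4 and 2 of 20 members called (3 adjusted over the list alone, camera adjusted p = 1.6e-05, and adjusted p = 0.0097 with an estimated correlation). Among pericyte and smooth muscle genes 5 of 16 were called higher, among them Acta2, smooth muscle actin (7.21-fold), Higd1b (3.21-fold) and Rgs5, a pericyte regulator of G-protein signalling (1.95-fold), and the list rose (median log2 change 0.25, adjusted p = 5e-05, and adjusted p = 0.002 with an estimated correlation). With pigment epithelium and lens RNA as covariates 3 of the 16 were called and the median was 0.69. Rgs5 lost its call with these covariates, with limma-trend on TPM, and without control replicate 3 or IgG replicate 3 (adjusted p up to 0.15). Angpt2, the ligand that anti-ANG2 binds, stood at 14 ± 3.96 against 5.37 ± 0.679 CPM (2.59-fold) and missed the threshold (adjusted p = 0.052). Neither VEGF receptor was called: Kdr was at 1.07-fold (adjusted p = 0.89) and Flt1 at 1-fold (adjusted p = 1). The pan-endothelial list was not called (median log2 change 0.53, adjusted p = 0.11). Proliferation genes rose as a list (median log2 change 1.03, 2 of 21 called, adjusted p = 0.00046, and adjusted p = 0.0029 with an estimated correlation), with Ube2c, a mitotic ubiquitin-conjugating enzyme, up 10.6-fold. The proliferation median was 0.62 without IgG replicate 2 and 0.67 without IgG replicate 4, and the pericyte median 0.42 to 0.54 without control replicate 1, 2 or 4 or IgG replicate 1.

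Genes of inflammation and gliosis rose at P17. Of 20 genes of microglia and macrophages, 16 were called higher (18 adjusted over the list alone) and all 20 had a positive estimate, with a median log2 change of 1.87 (adjusted p = 1.1e-32, and adjusted p = 0.00025 with an estimated correlation). C1qb, a chain of complement C1q made by microglia, rose 4.76-fold (121 ± 33.3 against 25.5 ± 7.77 CPM, adjusted p = 2.4e-08), and Lyz2, the lysozyme of myeloid cells, rose 7.25-fold. Both microglial states were higher. Among 11 homeostatic genes 5 were called, such as Fcrls (7.97-fold) and the fractalkine receptor Cx3cr1 (2.59-fold), and among 19 activation genes 9 were called, such as Lgals3, galectin-3 (10.1-fold), Trem2 (3.64-fold) and its partner Tyrobp (4.03-fold). The lists gave adjusted p = 6.8e-08 (adjusted p = 0.0096 with an estimated correlation) and adjusted p = 1.1e-16 (adjusted p = 0.002 with an estimated correlation). Complement rose with 6 of 13 called (median log2 change 1.71, adjusted p = 1.6e-12, and adjusted p = 0.00052 with an estimated correlation), led by C4b (17.5-fold). Gfap, the intermediate filament of reactive Müller glia and astrocytes, rose 5.35-fold (213 ± 94.9 against 39.8 ± 16.2 CPM, adjusted p = 7e-05), and 12 of 22 reactive glia genes were called (median log2 change 1.66, adjusted p = 4.3e-15, and adjusted p = 0.0023 with an estimated correlation), among them Fgf2 (4.11-fold) and S100a6 (4.57-fold). Interferon response (median log2 change 0.88), cytokines and chemokines (1.16) and p53 targets (0.4) rose too, with adjusted p = 0.031, adjusted p = 0.0096 and adjusted p = 0.031 with an estimated correlation. Cdkn1a, the p53-induced inhibitor of the cell cycle, rose 2.67-fold. With pigment epithelium and lens RNA as covariates 10 of the 20 microglia and macrophage genes, 3 of the 11 homeostatic, 5 of the 19 activation, 5 of the 13 complement and 8 of the 22 reactive glia genes were called. The activation median moved from 1.02 to 0.59 with these covariates and the reactive glia median to 1.17. Without IgG replicate 2 the medians of reactive glia and cytokines were 0.86 and 0.67, and the p53 median was 0.09 to 0.22 without control replicate 2 or 4 or IgG replicate 1 or 4.

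Fewer genes fell at P17. Those with the largest folds and non-overlapping libraries included Cck, the neuropeptide cholecystokinin (0.37-fold, 7.2 ± 2.04 against 19.5 ± 4.61 CPM, adjusted p = 0.012), Kcnj6, a G-protein-gated potassium channel (0.48-fold), Tenm2, a synaptic adhesion protein (0.455-fold), and Fat4, an atypical cadherin (0.379-fold). Each of these lost its call when RNA of pigment epithelium and lens was taken into account, where the adjusted p of Cck was 0.056. Kcnj6, Tenm2 and Fat4 lost it also with limma-trend on TPM. Kcnj6 lost its call without any 1 of 6 of the 8 libraries (adjusted p up to 0.14) and Fat4 without any 1 of 4 (up to 0.16). Tenm2 lost it without any 1 of 3 (adjusted p up to 0.09) and Cck without either of 2 (up to 0.056). Bipolar cell genes were lower as a list (median log2 change −0.32, 0 of 16 called, 1 adjusted over the list alone, adjusted p = 0.0073), but not with an estimated correlation (adjusted p = 0.3). Some lists that rose with the preset correlation also lost their call with an estimated one. They were rods (median log2 change 0.36, adjusted p = 0.21 with an estimated correlation), cones (0.39, with Gnat2, cone transducin, up 1.82-fold; adjusted p = 0.17 with an estimated correlation), oxidative phosphorylation (0.33, or 0.21 without control replicate 3; adjusted p = 0.28 with an estimated correlation) and red blood cells (1.76, or 1.04 without IgG replicate 2; adjusted p = 0.087 with an estimated correlation). Marker genes of neighbouring tissue also differed between the groups. Rpe65, the retinoid isomerase of the pigment epithelium, was 96.5 ± 32.2 against 20.8 ± 9.48 CPM (4.65-fold, adjusted p = 0.012), and 9 of 14 pigment epithelium genes were higher adjusted over the list alone (median log2 change 1.01, adjusted p = 2.1e-05, and adjusted p = 0.18 with an estimated correlation). The Rpe65 call was lost without control replicate 3 or 4 or IgG replicate 3 (adjusted p up to 0.065). The lens crystallin Cryaa stood at 368 ± 674 CPM in OIR and 0.0337 ± 0.0673 CPM in controls. The 16 crystallins had a median log2 change of 8.18, and their mean log2 CPM ran from −0.45 to 7.384 (replicate 4) over the IgG retinas. The lens list had a mean log2 CPM of −0.47 ± 1.12 in OIR and −0.49 ± 0.4 in controls.

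In total edgeR called 555 genes at P17, 496 higher and 59 lower, and in 11.4% of all genes the libraries did not overlap, against 2.86% by chance. With pigment epithelium and lens RNA as covariates 142 genes were called, and without the 5 libraries in doubt 1073 (844 higher). The share of called genes that were higher was 89.4%, but 73.6% of 1062 genes with DESeq2, 76% of 1049 with voom, 70.3% of 593 in a fit to these groups alone, and 44.9% of 365 with limma-trend on TPM, which moved the median of all genes from −0.048 to −0.22. The count fell to 225 without control replicate 3, 290 without control replicate 4, 219 without IgG replicate 2 and 255 without IgG replicate 3. All named genes of the hypoxia, microglia, complement and reactive glia lists except Vegfa, Cx3cr1 and Aif1 kept their call in each setting run for named genes and without any library.

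**Figure D1:**
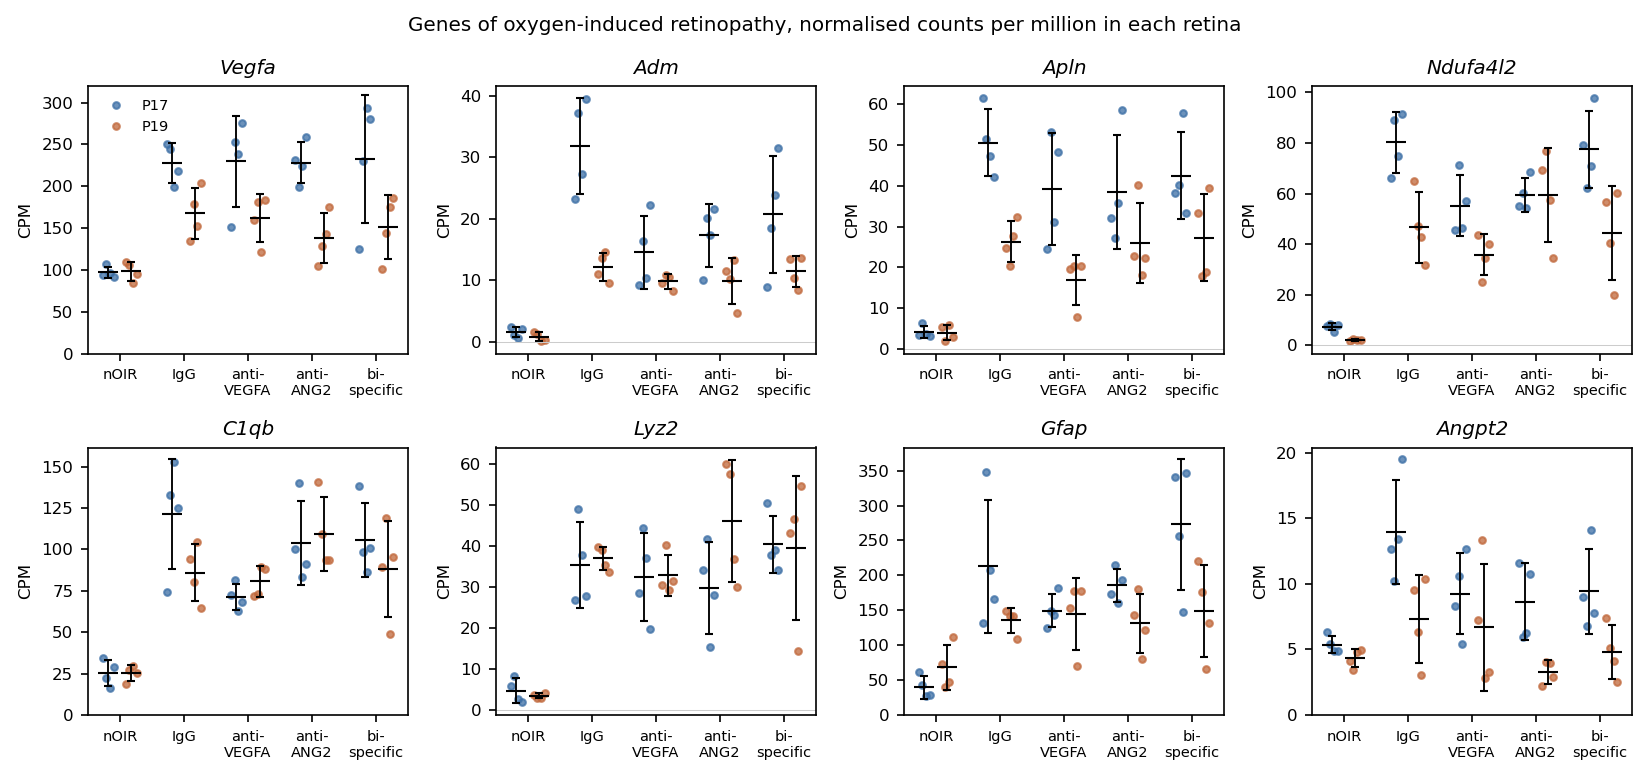
Normalised counts (CPM, linear axis from 0) of 8 named genes in the 5 groups at P17 (blue) and P19 (orange), with a point per retina (4 per group) and bars for the mean and SD. Ndufa4l2, Adm, Apln and C1qb lay higher in all 4 IgG-treated OIR retinas than in all 4 control retinas at both ages.

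At P19 the inflammatory and vascular parts of the OIR response were again higher. Ndufa4l2 rose 22.6-fold (46.6 ± 13.9 against 2.05 ± 0.376 CPM, n = 4 each, adjusted p = 2.4e-14), Adm 15.4-fold (12.2 ± 2.28 against 0.788 ± 0.737 CPM, adjusted p = 1.9e-06) and Apln 6.67-fold (adjusted p = 3.1e-06). Of the microglia and macrophage genes, 13 of 20 were called higher (17 adjusted over the list alone) and all 20 were positive (median log2 change 1.76, adjusted p = 3.9e-38, and adjusted p = 7.4e-05 with an estimated correlation). Lyz2 rose 10.5-fold (37 ± 2.91 against 3.53 ± 0.615 CPM, adjusted p = 7.4e-08), C1qc 3.9-fold, and Adgre1, the macrophage antigen F4/80, 7.4-fold. Complement (4 of 13 called, median log2 change 1.76, adjusted p = 0.00041 with an estimated correlation) and activated microglia (6 of 19, 0.84, adjusted p = 0.0083 with an estimated correlation) rose. So did interferon response (5 of 22, 0.52, or 0.31 without control replicate 1; adjusted p = 0.025 with an estimated correlation), with Ifitm3 up 4.31-fold and Psmb8, an immunoproteasome subunit, up 3.52-fold. Reactive glia genes rose as a list (3 of 22 called, 9 adjusted over the list alone, median log2 change 0.64, adjusted p = 4e-08, and adjusted p = 0.027 with an estimated correlation), among them Edn2, the endothelin made by stressed photoreceptors (13.1-fold), while Gfap was at 1.99-fold and not called (adjusted p = 0.17). Adgre1, Edn2 and Psmb8 lost their calls without any 1 of 4, 4 and 3 of the 8 libraries (adjusted p up to 0.12, 0.075 and 0.15), and Adgre1 with Y-linked counts as a covariate.

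At P19 the endothelial list was called (median log2 change 0.67, 2 of 24 members called, 4 adjusted over the list alone, adjusted p = 3.9e-05, and adjusted p = 0.001 with an estimated correlation). Its called members were Emcn, endomucin (7.12-fold), and Cldn5, the tight junction protein claudin-5 (2.4-fold, 9.99 ± 1.04 against 4.16 ± 1.23 CPM, adjusted p = 0.034). Both depend on single libraries: Emcn lost its call without any 1 of 4 of the 8 libraries (adjusted p up to 0.18), and Cldn5 without any 1 of 6 (adjusted p up to 0.14) and with Y-linked counts as a covariate. The mean log2 CPM of the endothelial list with IgG was 1.8 ± 0.2 at P17 and 1.73 ± 0.04 at P19. In control retinas it was 1.52 ± 0.27 and 1.12 ± 0.1. The list call at P19 thus goes with a lower level in controls, not with a higher level in OIR retinas than at P17. Tip cell genes (median log2 change 0.49, adjusted p = 0.025 with an estimated correlation) and pericyte genes (0.49, adjusted p = 0.00045 with an estimated correlation) rose, the latter with Higd1b up 5.97-fold and Rgs5 up 2.11-fold. Rgs5 lost its call without IgG replicate 1 (adjusted p = 0.058). Immediate early genes rose as a list with no member called over all genes (0 of 16, 7 adjusted over the list alone, median log2 change 0.79, adjusted p = 2.6e-05, and adjusted p = 0.027 with an estimated correlation). Vegfa was called at 1.7-fold (168 ± 30.4 against 98.6 ± 11.4 CPM, adjusted p = 0.047), and lost the call when any 1 of the 8 libraries was left out. Hypoxia targets had a median log2 change of 0.19 with 4 of 30 called (adjusted p = 0.00017, but adjusted p = 0.17 with an estimated correlation), and glycolysis was not called (−0.04, adjusted p = 0.26). Lower genes included Nefh, the neurofilament heavy chain of ganglion cells (0.537-fold, 148 ± 19.3 against 275 ± 61.3 CPM, adjusted p = 0.025), Slc17a8, a vesicular glutamate transporter of amacrine cells (0.328-fold), and the potassium channel genes Kcna2 (0.57-fold) and Kcnab3 (0.559-fold). Ganglion cell and amacrine lists had medians of −0.19 and −0.26 and lost their calls with an estimated correlation (adjusted p = 0.61 and adjusted p = 0.58 with an estimated correlation). Nefh, Slc17a8, Kcna2 and Kcnab3 each lost the call with Y-linked counts as a covariate, and without at least 5 of the 8 single libraries (adjusted p up to 0.13 for Nefh, 0.14 for Slc17a8, 0.29 for Kcna2 and 0.16 for Kcnab3). The list calls were lost too without control replicate 3 or IgG replicate 1, for ganglion cells also without control replicate 2 or IgG replicate 2 (adjusted p up to 0.18) and for amacrine cells also without IgG replicate 3 (adjusted p up to 0.18).

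At P19 edgeR called 216 genes, 193 higher and 23 lower, with 2968 at an unadjusted p under 0.05. DESeq2 called 516 (75.2% higher), voom 1132 (70.1%), limma-trend on TPM 340, a fit to these groups alone 737, a fit with the mitochondrial share 807, one with Y-linked counts 96, and without the libraries in doubt 359 were called. Each library moved the count by over 1.5 times: without control replicates 1 to 4 it was 69, 85, 113 and 108, and without IgG replicates 1 to 4 it was 57, 116, 108 and 421.

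The ages shared much of the OIR response. Of the 496 genes higher at P17 and the 193 higher at P19, 88 were shared, against 4.07 from n1 × n2 / N. Of all 555 genes called at P17, 506 changed in the same direction at P19 and 273 did so at an unadjusted p under 0.05. Tested directly, the OIR effect differed between ages for 1 gene by edgeR, with 1335 at an unadjusted p under 0.05, and for 32 by DESeq2, 27 by voom and 9 by limma-trend on TPM. The gene was 2900052N01Rik, a long noncoding RNA named here because the count is 1. As a list, glycolysis was lower in the P19 effect than in the P17 effect in all 18 genes (median log2 difference −0.58, 0 called, 12 adjusted over the list alone, camera adjusted p = 3e-17, fry adjusted p = 0.022, but adjusted p = 0.1 with an estimated correlation). Hypoxia targets differed the same way in 26 of 30 genes (−0.46, adjusted p = 2.1e-07, but adjusted p = 0.19 with an estimated correlation). Between control retinas, glycolysis genes were higher at P19 than at P17 (median log2 change 0.36, 18 of 18 positive, adjusted p = 1.5e-15, fry adjusted p = 0.017, but adjusted p = 0.085 with an estimated correlation). On these estimates part of the difference lies in the controls. There Hk2, a hexokinase, rose 2.55-fold with age (88.7 ± 10 against 34.8 ± 2.26 CPM, adjusted p = 0.0032). In the same control retinas Ndufa4l2 fell to 0.281-fold, from 7.32 ± 1.41 to 2.05 ± 0.376 CPM (adjusted p = 0.0017). Hk2 and Ndufa4l2 both lost their calls with a replicate block.

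**Figure D2:**
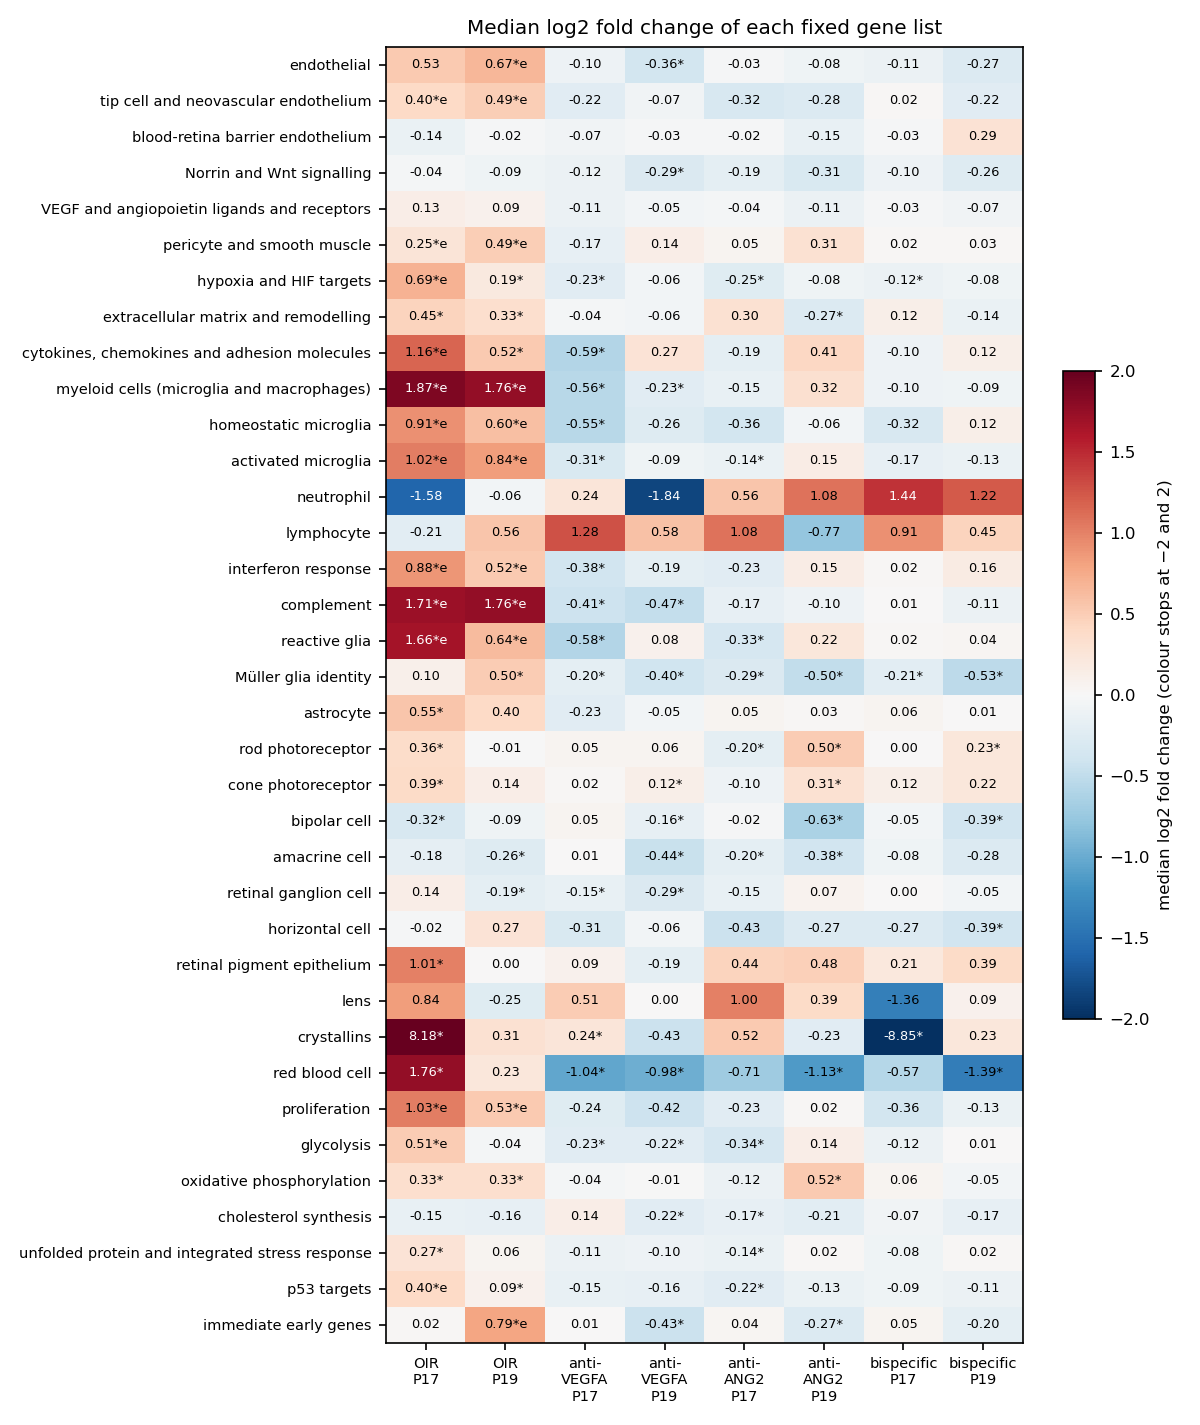
Median log2 fold change of each of the 36 gene lists (vertical) in each of the 8 primary comparisons (horizontal), with colours limited to −2 to 2. A star marks camera adjusted p under 0.05 with the preset correlation and e a call that also holds with an estimated correlation. Every e stands in the 2 OIR columns, for example at the microglia and macrophage list with medians of 1.87 and 1.76.

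Anti-VEGFA was compared with IgG to ask what blocking VEGFA changes in OIR. At P17 the genes of inflammation and gliosis that were high in OIR had negative estimates with the antibody. The same 4 IgG retinas served the OIR comparison. In simulations without an antibody effect this sharing alone gave genes raised by OIR a median log2 change of −0.12. All 22 reactive glia genes were lower than with IgG (median log2 change −0.58, 0 called, 1 adjusted over the list alone, camera adjusted p = 3.3e-06, but adjusted p = 0.15 with an estimated correlation). Microglia and macrophage genes had a median of −0.56 with 18 of 20 negative (0 called, 5 lower adjusted over the list alone, adjusted p = 9e-07, but adjusted p = 0.15 with an estimated correlation). Cytokines and chemokines (median −0.59, 17 of 18 negative, adjusted p = 0.012, but adjusted p = 0.15 with an estimated correlation) and hypoxia targets (−0.23, 23 of 30 negative, adjusted p = 4.9e-05, but adjusted p = 0.19 with an estimated correlation) went the same way. No list held with an estimated correlation or with fry, where the smallest adjusted p was 0.14. Without IgG replicate 2 the reactive glia and cytokine medians were both −0.29 (adjusted p = 0.03 and adjusted p = 0.23), and the cytokine call was also lost without anti-VEGFA replicate 1 or 2 (adjusted p = 0.085 and adjusted p = 0.061). Single genes did not pass: Vegfa was at 1.01-fold (230 ± 54.2 against 228 ± 23.9 CPM), Apln at 0.776-fold, Angpt2 at 0.665-fold and Gfap at 0.703-fold, each with adjusted p = 1. Crystallins had a positive median (0.24) and mean (0.12) while camera put them lower (adjusted p = 0.033, adjusted p = 0.65 with an estimated correlation), and their median ran from −6.53 without anti-VEGFA replicate 4 to 3.75 without IgG replicate 4. The smallest p-values belonged to Gm15384 (0.673 ± 0.363 against 0 CPM), Pcsk7, a proprotein convertase (24 ± 1.5 against 12.6 ± 2.22 CPM), and Gm43560 (2.83-fold), all with adjusted p = 0.99. edgeR and voom called 0 genes, with 1128 at an unadjusted p under 0.05 in edgeR against 1175 by chance, limma-trend 0 and DESeq2 2.

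At P19, anti-VEGFA retinas had lower estimates for endothelial genes (19 of 24 negative, median log2 change −0.36, 0 called, 0 adjusted over the list alone, adjusted p = 0.025, fry adjusted p = 0.034, but adjusted p = 0.27 with an estimated correlation). Plvap, the fenestral diaphragm protein of leaky vessels, was at 2.53 ± 1.42 against 5.37 ± 0.731 CPM (0.475-fold, adjusted p = 0.33), and Apln at 0.645-fold (adjusted p = 0.45), or 0.755-fold without anti-VEGFA replicate 3. The endothelial median was −0.22 without IgG replicate 1, and the list call was lost without IgG replicate 2 (adjusted p = 0.058) or anti-VEGFA replicate 4 (adjusted p = 0.098). Immediate early genes were lower in 14 of 16 cases (median −0.43, adjusted p = 0.00078, fry adjusted p = 0.034, but adjusted p = 0.27 with an estimated correlation), and Müller glia identity genes in 13 of 14 (−0.4, adjusted p = 0.00021, but adjusted p = 0.49 with an estimated correlation). Lower too were red blood cell genes (−0.98, adjusted p = 0.0022, but adjusted p = 0.44 with an estimated correlation). Among the smallest p-values were those of C1ql2 (0.489-fold) and Tcof1 (0.499-fold), with adjusted p = 0.22. edgeR called 0 genes with 2615 at an unadjusted p under 0.05, voom 0, limma-trend on TPM 2 and DESeq2 38. Without anti-VEGFA replicate 1 edgeR called 88 (5 higher, 83 lower), and without replicate 2 it called 2. Mitochondrial transcripts took 7.82% ± 1.93 of the counts in this group, against 5.42% ± 0.994 with IgG.

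Anti-ANG2 was compared with IgG in the same way. At P17, glycolysis genes were lower in 17 of 18 cases (median log2 change −0.34, 0 called, 6 lower adjusted over the list alone, adjusted p = 1.9e-09, but adjusted p = 0.35 with an estimated correlation). Hypoxia targets were lower in 26 of 30 (−0.25, adjusted p = 0.00011, but adjusted p = 0.35 with an estimated correlation), and reactive glia genes in 18 of 22 (−0.33, adjusted p = 0.023, but adjusted p = 0.56 with an estimated correlation). The reactive glia call was lost without IgG replicate 2 (median −0.09, adjusted p = 0.57) or anti-ANG2 replicate 3 (adjusted p = 0.066). Vegfa was at 1-fold (adjusted p = 1), Angpt2 at 0.621-fold (adjusted p = 0.69) and Kdr at 0.751-fold (adjusted p = 0.68). The smallest p-values were those of Gm15384 (1.32 ± 0.383 against 0 CPM), Pet100, an assembly factor of cytochrome c oxidase (128 ± 14 against 59 ± 6.21 CPM, 2.17-fold), and Gm40671 (5.9-fold), with adjusted p = 0.44. edgeR called 0 genes with 1795 at an unadjusted p under 0.05, limma-trend 0, DESeq2 19, voom 63 and an edgeR fit to these groups alone 278.

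At P19, anti-ANG2 retinas had 19 genes called lower and 4 higher than with IgG. Lrrn3, a neuronal leucine-rich repeat protein, fell to 0.427-fold (42.8 ± 22 against 100 ± 14.2 CPM, n = 4 each, adjusted p = 0.0034), and Qpct, glutaminyl cyclase, to 0.474-fold (78.1 ± 8.16 against 165 ± 16.4 CPM, adjusted p = 0.0081). Isl1, a transcription factor of ON bipolar cells, fell to 0.56-fold (94.2 ± 12.6 against 168 ± 12.6 CPM, adjusted p = 0.025), and Grm4, a metabotropic glutamate receptor, to 0.245-fold. Bipolar cell genes were lower in 16 of 16 cases (median log2 change −0.63, 1 called, 8 lower adjusted over the list alone, adjusted p = 5.6e-08, fry adjusted p = 0.026, but adjusted p = 0.33 with an estimated correlation). Rod genes had the opposite direction in 20 of 20 cases (median 0.5, 0 called, 15 adjusted over the list alone, adjusted p = 5.9e-12, but adjusted p = 0.33 with an estimated correlation), as did oxidative phosphorylation (0.52, or 0.34 without anti-ANG2 replicate 1; 13 adjusted over the list alone, adjusted p = 3e-08, but adjusted p = 0.33 with an estimated correlation). Müller glia identity (−0.5, adjusted p = 0.00011) and amacrine genes (−0.38, adjusted p = 0.00055) were lower, both with adjusted p = 0.33 with an estimated correlation. The genes called higher were Wdr66 (1.97-fold), Cyb5r1 (1.7-fold), Ip6k2, an inositol hexakisphosphate kinase (1.6-fold, 72.3 ± 9.11 against 45.2 ± 5.16 CPM), and 4930529C04Rik. Angpt2 itself stood at 0.448-fold (3.28 ± 0.887 against 7.33 ± 3.34 CPM, adjusted p = 0.19).

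For anti-ANG2 at P19 edgeR called 23 genes, 4 higher and 19 lower, with 2935 at an unadjusted p under 0.05. The mitochondrial share differed between the groups (8.16% ± 1.79 against 5.42% ± 0.994), and with it as a covariate 4 genes were called. The tools disagreed on size and direction: DESeq2 called 557 (69.3% higher), voom 22 (50% higher), limma-trend on TPM 570 (4.21% higher, against 17.4% with edgeR), which moved the median of all genes from 0.027 to −0.19, and edgeR on these groups alone 1. Without anti-ANG2 replicate 4 the count was 453 (256 higher, 197 lower), and without replicates 1, 2 and 3 it was 5, 11 and 8. Without IgG replicate 2 it was 8 and without IgG replicate 4 it was 7. Without the libraries in doubt it was 8. Lrrn3 and Qpct kept their calls without any library but lost them with the mitochondrial covariate, where their log2 changes stayed near as large (−1.03 from −1.23 and −1 from −1.08). Isl1, Grm4, Wdr66, Cyb5r1 and Ip6k2 lost theirs with that covariate too. With it the log2 change of Isl1 was −0.63 (from −0.84) and that of Grm4 −1.58 (from −2.03). These genes also lost their calls without any 1 of at least 5 of the 8 libraries. In the fits without 1 library their adjusted p went up to 0.17, 0.46, 0.15, 0.36 and 0.2.

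**Figure D3:**
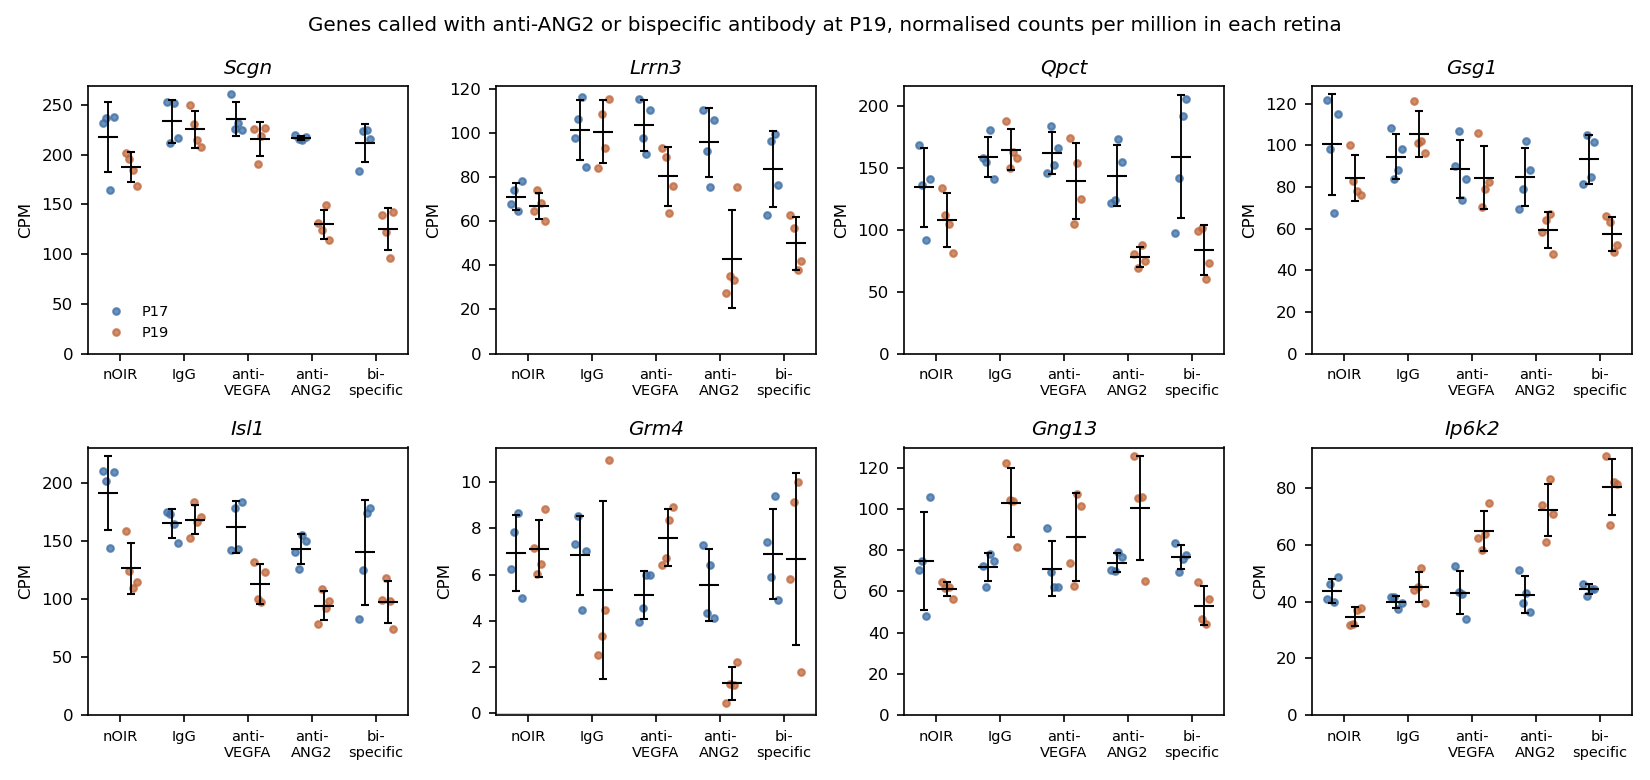
Normalised counts (CPM, linear axis from 0) of 8 genes called with anti-ANG2 or bispecific antibody at P19, in the 5 groups at P17 (blue) and P19 (orange), with a point per retina (4 per group) and bars for the mean and SD. At P19 Scgn was 225 ± 18.9 CPM with IgG and 125 ± 21 CPM with bispecific antibody, while Ip6k2 was 45.2 ± 5.16 and 80.4 ± 10 CPM.

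The bispecific antibody was compared with IgG to see what blocking both ligands changes. At P17 no inflammatory list was called with it: reactive glia genes had a median log2 change of 0.02 (adjusted p = 0.56) and microglia and macrophage genes −0.1 (adjusted p = 0.59). Hypoxia targets were lower in 24 of 30 cases (−0.12, 0 called, adjusted p = 0.015, but adjusted p = 0.91 with an estimated correlation), a call lost without IgG replicate 2 (adjusted p = 0.35) or bispecific replicates 1 or 3 (adjusted p = 0.1 and adjusted p = 0.075), with −0.19 without IgG replicate 1. Crystallins were far lower (median −8.85, or −4.99 without IgG replicate 4; 15 of 16 lower adjusted over the list alone, adjusted p = 9e-18, but adjusted p = 0.29 with an estimated correlation), and the IgG retinas they were compared with held Cryaa at 368 ± 674 CPM. Vegfa was at 1.02-fold, Angpt2 at 0.676-fold and Gfap at 1.28-fold, each with adjusted p = 1. Among the smallest p-values were Arhgap15, a Rac GTPase-activating protein (0.36-fold, 5.1 ± 1.26 against 14.2 ± 5.53 CPM, adjusted p = 0.59), and Atp2a1, a calcium pump of muscle (20.1 ± 39.2 against 0.15 ± 0.125 CPM, adjusted p = 0.59), whose mean rests on 1 retina with muscle RNA (78.9 CPM). edgeR called 0 genes with 921 at an unadjusted p under 0.05, voom 0, limma-trend 0 and DESeq2 16.

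At P19, 10 genes were called lower and 1 higher with the bispecific antibody than with IgG. Scgn, a calcium sensor of cone bipolar cells, fell to 0.555-fold (125 ± 21 against 225 ± 18.9 CPM, n = 4 each, adjusted p = 0.00082), and Gng13, the G-protein subunit of ON bipolar cells, to 0.516-fold (53.1 ± 9.38 against 103 ± 16.7 CPM, adjusted p = 0.025). Gabrb2, a GABA-A receptor subunit, fell to 0.503-fold, Qpct to 0.507-fold, Lrrn3 to 0.498-fold and S1pr3, a sphingosine-1-phosphate receptor, to 0.495-fold. Ip6k2 rose 1.78-fold (80.4 ± 10 against 45.2 ± 5.16 CPM, adjusted p = 0.0046). Bipolar cell genes were lower in 15 of 16 cases (median log2 change −0.39, 1 called, 7 lower adjusted over the list alone, adjusted p = 8.2e-09, fry adjusted p = 0.032, but adjusted p = 0.15 with an estimated correlation). Müller glia identity genes were lower in 14 of 14 (−0.53, 5 adjusted over the list alone, adjusted p = 7e-09, fry adjusted p = 0.033, but adjusted p = 0.15 with an estimated correlation). Bispecific replicate 3, the library with the fewest counts (9155045), had the lowest mean log2 CPM of this list. It stood at 6.002, against 6.529 to 7.01 in the other bispecific retinas and a mean of 7.13 with IgG. Horizontal cell genes were lower in 5 of 6 (−0.39, adjusted p = 0.041, but adjusted p = 0.15 with an estimated correlation, and not called without IgG replicate 2 or 3 or bispecific replicate 1 or 3, adjusted p up to 0.098) and red blood cell genes in 6 of 6 (−1.39, adjusted p = 3.6e-06, but adjusted p = 0.15 with an estimated correlation).

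For the bispecific antibody at P19 edgeR called 11 genes, 1 higher and 10 lower, with 1936 at an unadjusted p under 0.05. All 4 IgG retinas carried Y-linked counts and the 4 bispecific retinas carried almost none, and with Y-linked counts as a covariate 0 genes were called. DESeq2 called 73 (60.3% higher, against 9.09% with edgeR), voom 12, limma-trend on TPM 4, a fit to these groups alone 5 and one with the mitochondrial share 18. The 5 held 0 of the 11 genes. Without the libraries in doubt 9 were called, and without bispecific replicate 3 the count was 8, each with 3 of the 11 genes among them. Without IgG replicates 1, 2 and 4 the counts were 3, 3 and 5, and without bispecific replicate 4 the count was 4. S1pr3, Lrrn3, Qpct and Gng13 each lost the call without any 1 of 5 of the 8 libraries (adjusted p up to 0.17, 0.22, 0.17 and 0.16). Scgn and Ip6k2 kept their calls without any library, the only 2 of the 9 named genes that did. Gabrb2 thus also lost its call in a fit without 1 library.

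Both P19 lists share the same IgG retinas. Of the 19 genes lower with anti-ANG2 and the 10 lower with the bispecific antibody, 5 were shared, and so was Ip6k2 among the higher ones (expected by n1 × n2 / N 0.00809 and 0.00017). That expectation takes no account of the shared retinas, and simulations with shared retinas and no antibody effect called 0 genes, so they give no value for sharing. Across genes, which are not independent replicates, the fold changes of the antibodies had a covariance of 0.717, against 0.431 in the simulation. With each antibody compared with a separate set of 2 IgG retinas, where sharing adds nothing, the covariance in these data was 0.425 on average. In the 6 such pairs of comparisons the calls shared 0 genes in 4 and 1 gene in 2, out of at most 11 called.

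The antibodies were also compared with one another. At P19 anti-VEGFA and anti-ANG2 differed in 56 genes called by edgeR (43 higher with anti-VEGFA, 13 lower). Scgn was 216 ± 16.9 against 130 ± 14.5 CPM (1.66-fold, adjusted p = 0.015), Grm4 5.81-fold, and Neurod4, a transcription factor of bipolar cells, 404 ± 32.8 against 247 ± 39.6 CPM (1.64-fold, adjusted p = 0.02). Ube3a, a ubiquitin ligase, was 1.57-fold higher. Lower with anti-VEGFA were Naaa, a lipid amidase of macrophages (0.493-fold), and the ribosomal protein genes Rpl28 (0.535-fold) and Rpl38 (0.532-fold). Microglia and macrophage genes were lower with anti-VEGFA (median log2 difference −0.59, adjusted p = 6.2e-05, but adjusted p = 0.53 with an estimated correlation), as was oxidative phosphorylation (−0.56, adjusted p = 1.9e-09, but adjusted p = 0.53 with an estimated correlation). The call count was 0 without anti-ANG2 replicate 1 or 2, 11 without replicate 3, 1403 without replicate 4, 192, 8, 27 and 7 without anti-VEGFA replicates 1 to 4, and 0 without the libraries in doubt. It was 68 with RLE factors (58.8% higher, against 76.8%), 1076 with DESeq2 (40.6% higher), 415 with the mitochondrial share (40% higher) and 0 in a fit to these groups alone.

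Bispecific against anti-VEGFA at P19 gave 13 genes, 1 higher (Selenbp1, a methanethiol oxidase, 1.93-fold) and 12 lower, led by Ube3a (143 ± 11.9 against 255 ± 13 CPM, 0.562-fold, adjusted p = 0.00057), Scgn (0.58-fold, adjusted p = 0.0022) and Mapk8, the kinase JNK1 (0.512-fold). RLE factors gave 19 (36.8% higher, against 7.69%), DESeq2 167 (52.7% higher), voom 130, a fit to these groups alone 0, Y-linked counts as a covariate 5, and leaving out the libraries in doubt 335. Without bispecific replicate 3 the count was 464, without replicates 1, 2 and 4 it was 6, 2 and 4, and without anti-VEGFA replicates 1, 3 and 4 it was 68, 7 and 3. Bispecific against anti-ANG2 at P19 gave 0 genes by edgeR with 2725 at an unadjusted p under 0.05, 0 by voom and limma-trend and 419 by DESeq2. It gave 739 without anti-ANG2 replicate 4 and 225 without bispecific replicate 4. Grm4 (5.1-fold), Spice1, a centriole protein (2.73-fold), and Sgsm1 (3.66-fold) had the smallest p (adjusted p = 0.062).

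At P17, edgeR called 0 genes between bispecific and anti-VEGFA (676 at an unadjusted p under 0.05), 0 between bispecific and anti-ANG2 (662) and 0 between anti-VEGFA and anti-ANG2 (657). DESeq2 called 15, 20 and 7. Reactive glia genes were higher with bispecific antibody than with anti-VEGFA (median log2 difference 0.71, adjusted p = 7.6e-11, but adjusted p = 0.066 with an estimated correlation), as were microglia and macrophage genes (0.52, adjusted p = 1.6e-06, but adjusted p = 0.2 with an estimated correlation). The smallest p-values belonged to Arsi, Cryaa and Pm20d2 in the first comparison, Arhgap15, Acta1 and Fbxw21 in the second, and Taf8, Xist and Idi1 in the third, all with adjusted p = 1. Xist was 0.357 ± 0.476 CPM with anti-VEGFA and 685 ± 57 CPM with anti-ANG2.

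The genes raised by OIR were then followed in the antibody groups, with OIR genes called on 2 of the 4 IgG retinas and antibody effects measured against the other 2. At P17 the median log2 change of these genes was −0.26 with anti-VEGFA (−0.63 to −0.04 over the 6 ways of dividing the IgG retinas, below 0 in 4 of 4 retinas), −0.17 with anti-ANG2 (−0.38 to −0.02) and −0.12 with the bispecific antibody (−0.27 to −0.02, or −0.07 without its replicate 3). At P19 it was −0.18 with anti-VEGFA (−0.5 to 0.15), 0.31 with anti-ANG2 (0.13 to 0.59) and −0.1 with the bispecific antibody (−0.17 to 0.04, below 0 in 2 of 4 retinas). The bispecific value at P19 rests on replicate 3 (−0.73, against 0.06, −0.04 and 0.08 in the others), and was 0.05 without it. In 10 simulations without any antibody effect the P17 median of raised genes averaged 0.01 to 0.02 with such separate sets (lowest −0.01, highest 0.06). It averaged −0.12 when all 4 IgG retinas served both comparisons (lowest −0.15, highest −0.09). These simulations show only what sharing IgG retinas adds. Their narrow range does not measure chance between real retinas, where many genes varied together, so it does not test the medians above. Genes lowered by OIR at P17 had medians of 0.33 (0.16 without anti-VEGFA replicate 3), 0.49 and 0.23 with the same antibodies, and 1 of the 6 divisions gave 0 such genes. At P19 genes lowered by OIR had medians of −0.22 (−0.08 without anti-VEGFA replicate 1), −0.15 (−0.02 without anti-ANG2 replicate 1) and 0.12 (−0.02 without bispecific replicate 3), on divisions with as few as 1 such gene. An exact permutation test of antibody against IgG retinas, run as a departure from the plan on OIR genes called at the other age, gave its smallest p for anti-VEGFA at P17 (difference −0.3, exact two-sided p = 0.0857, adjusted p = 0.685). With 4 retinas against 4 the smallest exact p is 0.0286, so no single shift could pass over 12 such tests and they decide nothing on the medians above.

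**Figure D4:**
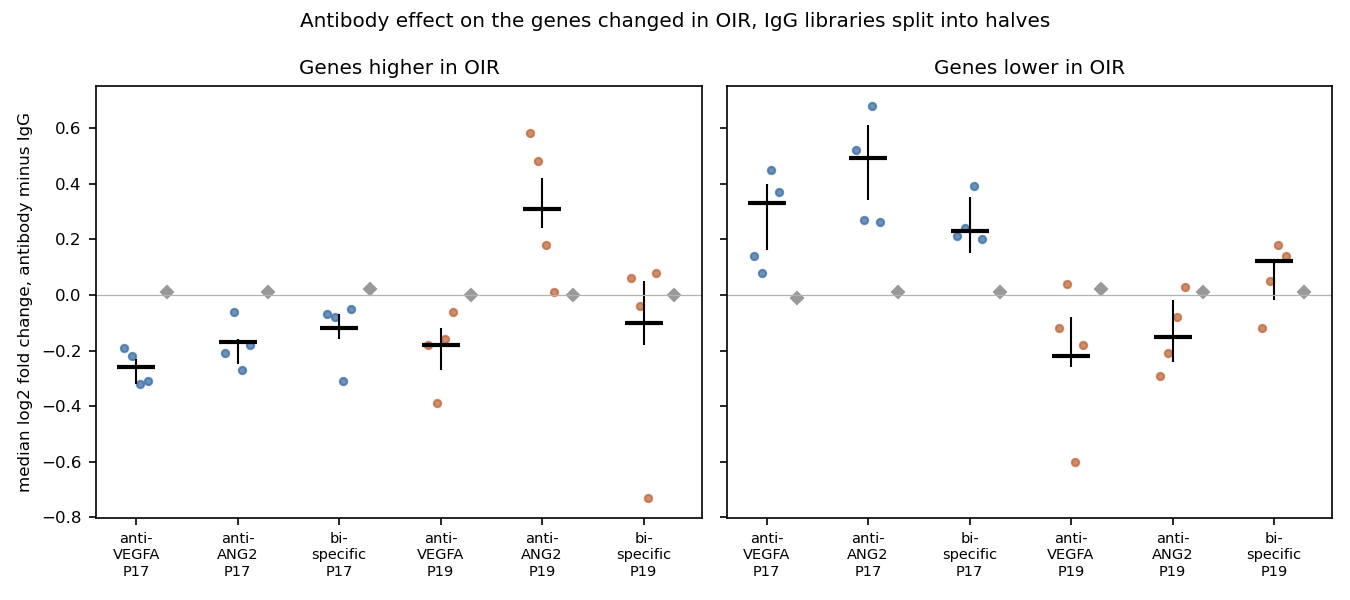
Median log2 change with antibody (vertical axis) of genes raised or lowered by OIR, with OIR genes called on separate IgG retinas. Points are single retinas (4 per group, P17 blue, P19 orange), bars the average median, lines the leave-one-out range and grey diamonds the value simulated without an antibody effect. The diamonds do not show the spread expected by chance. For genes raised by OIR at P17 the bars stand at −0.26, −0.17 and −0.12.

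Whether an antibody effect differed between ages was tested directly. edgeR called 0 genes for anti-VEGFA (1122 at an unadjusted p under 0.05), 0 for anti-ANG2 (2581) and 0 for the bispecific antibody (1055), while DESeq2 called 5, 149 and 19. For anti-ANG2 voom called 118, and without anti-ANG2 P19 replicate 4 edgeR called 125. The smallest p-values were those of Xist, Insyn2b and F10 for anti-VEGFA (adjusted p = 0.76), Procr, the endothelial protein C receptor, Ippk and Cenpc1 for anti-ANG2 (adjusted p = 0.21), and Gabrb2, Gm14762 and Bcas1 for the bispecific antibody (adjusted p = 0.66).

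In control retinas, age from P17 to P19 changed 23 genes, 15 higher and 8 lower. Besides Hk2, the higher genes included Mef2c, a transcription factor of photoreceptors (1.92-fold, 51.3 ± 6.58 against 26.7 ± 6.41 CPM, adjusted p = 0.0028), Kcnab2, a potassium channel subunit (1.78-fold), Sgk1, a glucocorticoid-induced kinase (2.01-fold), and Mogat1 (2.67-fold). Lower were Col9a1, a collagen chain (0.438-fold, 119 ± 23.2 against 273 ± 45.8 CPM, adjusted p = 0.0017), Crym (0.454-fold) and Nnat, neuronatin (0.511-fold). Nnat lost its call without any 1 of 7 of the 8 libraries (adjusted p up to 0.16). With a replicate block 4 genes were called, and Hk2, Mef2c, Sgk1, Mogat1, Ndufa4l2, Crym and Nnat were not among them. Endothelial genes fell as a list (21 of 24 negative, median log2 change −0.45, 0 called, adjusted p = 0.0011, and adjusted p = 0.036 with an estimated correlation). Rod genes were higher in 18 of 20 cases (0.41, 4 called, 9 adjusted over the list alone, adjusted p = 1.5e-15, but adjusted p = 0.13 with an estimated correlation). DESeq2 called 142 (81.7% higher, against 65.2%), voom 196, limma-trend on TPM 124 (24.2% higher), edgeR on these groups alone 56, with the mitochondrial share 72 and without the libraries in doubt 69. Without control P17 replicate 1 the count was 13, without P17 replicate 4 it was 5, and without P19 replicates 2 and 4 it was 14 each.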

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

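The tests of sex and of RNA make-up, seen as the mitochondrial share, were written down before their results were seen. The tests of the IgG level, of pigment epithelium carry-over and of the library apart were chosen only after the result was seen.

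Each count of genes was compared with the counts that other splits of the same retinas gave. For OIR at P17 (555 genes, highest of the other splits 20) and P19 (216, highest 0) only the real split, 1 of 35, gave as many. The same held for the bispecific antibody at P19 (11, highest 3) and for age in control retinas (23, highest 2). A share of 1 of 35 is the smallest this test can give, and 19 comparisons were tested. That share alone therefore cannot exclude chance, though for OIR the real counts lay far above every other split. For the OIR difference between ages 3 of 100 drawn splits, the real one included, gave as many as the real 1 (highest 8). That count of 1 gene does not exclude chance either. Chance cannot be excluded for anti-ANG2 at P19 (23 genes, 2 of 35 splits, highest 656), for bispecific against anti-VEGFA at P19 (13, 7 of 35, highest 1964) or for anti-VEGFA against anti-ANG2 at P19 (56, 3 of 35, highest 839). Where edgeR called 0 genes every split gives as many, 35 of 35 or 100 of 100. The highest other counts were then 0 for each of the 3 antibodies at P17 and for anti-VEGFA at P19, and 6, 0 and 0 between antibodies at P17 (bispecific against anti-VEGFA, bispecific against anti-ANG2, anti-VEGFA against anti-ANG2). They were 1087 for bispecific against anti-ANG2 at P19, and 281, 774 and 48 for the differences of the anti-VEGFA, anti-ANG2 and bispecific effects between ages.

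Splits with several times the real count point to a structure of the P19 libraries that crosses the antibody groups. The 656 genes came from placing IgG replicate 1 with anti-ANG2 replicates 1, 2 and 3. The 1964 came from placing anti-VEGFA replicate 1 with bispecific replicates 1, 2 and 4, and the 1087 from placing anti-ANG2 replicates 1 and 2 with bispecific replicates 1 and 2. The 839 came from placing anti-ANG2 replicate 4 with anti-VEGFA replicates 1, 2 and 4. In the split with 1964 genes, anti-VEGFA replicates 2, 3 and 4 and bispecific replicate 3 had fewer counts than the retinas set against them. With 1087 genes, the sides lay apart on the first principal component (20.8 to 84.3 against −139.2 to −7). The sides of the splits with 656, 839 and 1964 genes overlapped on it, and the split with 839 did not follow counts. The labels name no batch. Neither sequencing depth, a batch nor an exchange of labels between retinas was tested as the origin of this structure. That doubt applies to each antibody comparison at P19.

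In 170 groups of 4 retinas (17 quantities in 10 groups), 17 held a retina whose gap to the nearest of the other 3 was large against the range of the group. That measure finds about 1 in 20 groups by chance, here 8.5. Among control retinas, Kdr was 54.1 CPM in P19 replicate 3 (others 97.8 to 101), Tek 2.29 in P17 replicate 1 (0.128 to 0.471), Esm1 1.21 in P19 replicate 1 (0 to 0.204) and Apln 6.35 in P17 replicate 2 (3.1 to 3.64). With IgG, P17 replicate 1 had Esm1 at 0.686 CPM (1.16 to 1.25), Pecam1 at 6.73 (4.5 to 4.88) and Aif1 at 1.2 (2.32 to 2.43), and P19 replicate 4 had Aif1 at 1.22 (2.21 to 2.34). Tek stood high in 1 retina of each antibody group at P19: 3.76 CPM in anti-VEGFA replicate 1 (0.0731 to 0.565), 4.18 in anti-ANG2 replicate 4 (0 to 0.126) and 3.94 in bispecific replicate 3 (0.0655 to 0.613). Apln was 7.66 CPM in anti-VEGFA P19 replicate 3 (19.5 to 20.2), Pecam1 8.3 in bispecific P17 replicate 1 (3.17 to 3.97) and Ccl2 1.16 in bispecific P19 replicate 4 (0.262 to 0.35). As mean log2 CPM over a list, pigment epithelium genes were at 5.41 in IgG P17 replicate 3 (4.59 to 4.73) and 3.77 in control P19 replicate 1 (4.92 to 5.01), and lens genes at 2.83 in anti-VEGFA P17 replicate 4 (−1.14 to −0.47).

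By a test of the difference itself, the OIR effect differed between ages for 1 gene, and for a list with the preset correlation. The noncoding RNA 2900052N01Rik had a log2 change of 1.65 at P17 (31 ± 9.2 against 9.84 ± 1.91 CPM) and −0.42 at P19 (20.8 ± 4.72 against 27.7 ± 2.88 CPM), a difference of −2.07 (SE 0.34, adjusted p = 0.006), and it was not called with pigment epithelium and lens covariates. Glycolysis genes differed by a median of −0.58, lower in the P19 effect (camera adjusted p = 3e-17, but 0.1 with an estimated correlation).

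The first pattern is a set of 24 genes lower at P19 with anti-ANG2 or bispecific antibody (median log2 change −0.95 with the antibody that called them). Sex of the mice as the whole cause is argued against, for the 24 genes as a set, by 5 other groups with both sexes. Each held 2 retinas with and 2 without Y-linked counts. There these genes differed by a mean of −0.05 (medians −0.16 to 0.09), against a bispecific effect of −0.69 and a bound of −0.34 (50% of it) set beforehand. The 0.09 came from anti-VEGFA at P19, whose replicate 3 held both Xist and Y-linked counts. The other medians ran from −0.16 to −0.02. With Y-linked counts as a covariate the 10 bispecific genes moved from a median of −0.91 (SE 0.17) to −0.71 (SE 0.2). Of these 10 calls 0 remained, in a design where antibody and sex coincide. The 10 genes were not tested apart from the 24 in the 5 other groups, so sex stays open for them. A shift of the mitochondrial share as the whole cause is argued against too, since 100% of the genes kept most of their change with it as a covariate. The 19 anti-ANG2 genes moved from −0.94 (SE 0.18) to −0.9 (SE 0.19). Of their 19 calls 2 remained, at a median adjusted p of 0.37, for a cause not tested. A shift in cell types was not tested as a cause. With anti-ANG2 at P19 the mean log2 CPM differed from IgG by 0.47 for rod genes and −0.57 for bipolar cell genes. High values in the IgG retinas cannot be told apart from an antibody effect: the median with anti-VEGFA was −0.27 (single retinas −0.48 to −0.1), on both sides of the −0.47 that would decide it, and the genes stood lower in control retinas than with IgG (median −0.29). An effect of blocking ANG2 on these genes stays open as an untested candidate explanation, for a set whose anti-ANG2 count chance splits can match.

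The second pattern is the higher level of pigment epithelium genes in OIR at P17. Carry-over of pigment epithelium that differs between retinas is a candidate explanation, as these genes varied together within groups (median pairwise correlation 0.69, against −0.07 to 0.09 for random lists). That test does not single it out, since rod genes varied together as much (0.68). With covariates made from pigment epithelium and lens genes the list's median fell from 1.01 to 0.23, an outcome that the making of the covariate fixes. A change of the pigment epithelium in OIR stays open, since the amount of attached epithelium was not measured apart from these genes.

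The third pattern is anti-VEGFA P19 replicate 3, which stood at 145 on the third principal component (other libraries −50.1 to 22.8). Shallow sequencing is argued against, since 12 libraries had fewer counts and lay between −31.1 and 22.8. Loss of molecules before sequencing cannot be told apart from other causes. Of genes at 5 to 10 CPM elsewhere 1.3% had no count here, against 0.156% at 10 to 20 CPM. At 20 to 40 CPM and above it was 0%, so the last step could not fall. Anti-ANG2 P19 replicate 1 had more such absent genes (33 against 29). It lay at −39.6 here but lowest on the second component (−104), before anti-VEGFA replicate 3 (−91.4, next −61.5). A mixture of the latter with another mouse, left open by Xist and Y-linked counts, and a biological explanation were not tested.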

How the results depend on the processing

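The covariate settings and the settings without the 5 libraries in doubt were chosen after the results were seen. Of 150 calls of named genes, 142 held with RLE factors, 131 with a replicate block, 131 with voom, 106 with limma-trend on TPM, 114 with pigment epithelium and lens covariates, 120 with Y-linked counts, 127 with the mitochondrial share, 125 without the libraries in doubt and 60 without each library in turn, and 0 reversed. Of 95 list calls, 24 held with an estimated correlation, 41 with fry, 93 with RLE factors, 84 with Y-linked counts and 62 without each library in turn. The cause of the changes below was not tested, except that fits to the compared groups alone and fits without libraries hold fewer samples.

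DESeq2 called more genes than edgeR in each of the 19 comparisons. For OIR it called 1062 at P17 and 516 at P19, against 555 and 216 with edgeR. For anti-VEGFA it called 2 and 38 against 0 and 0, for anti-ANG2 19 and 557 against 0 and 23, and for the bispecific antibody 16 and 73 against 0 and 11. Between antibodies at P17 it called 15 (bispecific against anti-VEGFA), 20 (bispecific against anti-ANG2) and 7 (anti-VEGFA against anti-ANG2), each against 0, and at P19 167, 419 and 1076 against 13, 0 and 56. For differences of effects between ages it called 32 (OIR), 5 (anti-VEGFA), 149 (anti-ANG2) and 19 (bispecific) against 1, 0, 0 and 0, and 142 against 23 for age in control retinas. Voom called 1049 and 1132 for OIR, 63 for anti-ANG2 at P17, 130 for bispecific against anti-VEGFA at P19, 27 and 118 for the OIR and anti-ANG2 differences between ages, and 196 for age. Limma-trend on TPM called 365 and 340 for OIR, 2 for anti-VEGFA, 570 for anti-ANG2 and 4 for the bispecific antibody at P19, 172 for anti-VEGFA against anti-ANG2 at P19, 9, 1 and 1 for the OIR, anti-ANG2 and bispecific differences between ages, and 124 for age. On TPM the median of all genes moved to −0.22 for OIR at P17, to −0.19 for anti-ANG2 at P19, from 0.05 to 0.25 for bispecific against anti-ANG2 at P19, from −0.0063 to 0.17 for anti-VEGFA against anti-ANG2 at P19 and from 0.007 to −0.26 for the anti-ANG2 difference between ages.

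Fits to the compared groups alone called 737 for OIR at P19, 2 and 278 for anti-VEGFA and anti-ANG2 at P17, 1 and 5 for anti-ANG2 and bispecific at P19, 6 for anti-VEGFA against anti-ANG2 at P17, 0 for this pair and 0 for bispecific against anti-VEGFA at P19, 13 for the OIR difference between ages and 56 for age. Without the low-count filter, 37 genes were called for anti-VEGFA against anti-ANG2 at P19. Replicate numbers did not pair the retinas: deviations of libraries with the same number had a mean correlation across genes of 0.01 at P17 and 0.02 at P19, with 4 of 40 pairs over 0.1 at each age. With the number as a replicate block, 124 genes were called for anti-VEGFA against anti-ANG2 at P19, 1 for the anti-ANG2 difference between ages and 4 for age in control retinas.

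With pigment epithelium and lens covariates, 142 genes were called for OIR at P17, 2 for anti-ANG2 at P17, 11 for anti-VEGFA against anti-ANG2 at P19 and 0 for the OIR difference between ages. With Y-linked counts, 96 were called for OIR at P19, 0 for bispecific at P19 and 5 for bispecific against anti-VEGFA at P19, and 4 lists (against 10) for anti-ANG2 at P17 and 9 (against 5) for bispecific at P19. With the mitochondrial share, 807 were called for OIR, 4 for anti-ANG2, 18 for bispecific, 3 for bispecific against anti-VEGFA and 415 for anti-VEGFA against anti-ANG2, all at P19, and 72 for age. Without the libraries in doubt, 1073 and 359 were called for OIR, 11 and 8 for anti-ANG2, 335 for bispecific against anti-VEGFA and 0 for anti-VEGFA against anti-ANG2 at P19, 12 and 2 for the OIR and bispecific differences between ages and 69 for age.

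Leaving out 1 library gave 219 (IgG replicate 2) to 653 genes for OIR at P17 and 57 (IgG replicate 1) to 421 (IgG replicate 4) at P19. At P19 it gave 0 to 88 for anti-VEGFA (without its replicate 1), 5 to 453 for anti-ANG2 (without its replicates 1 and 4), 3 to 14 for bispecific, 2 to 464 for bispecific against anti-VEGFA (without bispecific replicates 2 and 3), 0 to 739 for bispecific against anti-ANG2 (without anti-ANG2 replicate 4) and 0 to 1403 for anti-VEGFA against anti-ANG2 (without anti-ANG2 replicates 1 and 4). For differences between ages it gave 0 to 125 for anti-ANG2 (without its P19 replicate 4) and 0 to 2 for bispecific (without its P19 replicate 3), and for age 5 to 31.

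With an estimated correlation, 13 lists were called for OIR at P17 and 11 at P19, against 23 and 19, and 0 for each antibody at each age, against 13, 10 and 3 at P17 and 13, 9 and 5 at P19 for anti-VEGFA, anti-ANG2 and bispecific. With fry the P17 counts were 0, 0 and 0, and 2, 1 and 4 at P19. Without 1 library the lists numbered 6 to 14 for anti-ANG2 and 2 to 7 for bispecific at P17, and 7 to 15 for anti-VEGFA and 3 to 9 for bispecific at P19. The crystallin list of anti-VEGFA at P17 ran from adjusted p = 1.5e-11 to adjusted p = 0.55, and without IgG replicate 4 its direction reversed (adjusted p = 0.5).

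For genes lowered by OIR, using all 4 IgG libraries in both roles moved the medians to 0.52 (anti-VEGFA, from 0.33) and 0.5 (bispecific, from 0.23) at P17 and to 0.09, 0.17 and 0.33 at P19 (from −0.22, −0.15 and 0.12), as sharing controls does in simulation. Genes called at the other age gave 0.11, −0.05 and 0.04 at P17 (anti-ANG2 from 0.49) and 0.22 for anti-VEGFA at P19. For raised genes they gave 0.1 for anti-ANG2 (from 0.31), −0.08 for anti-VEGFA (from −0.18) and −0.14 for bispecific (from −0.1) at P19 and −0.06 for bispecific at P17 (from −0.12). Without the libraries in doubt the bispecific median at P17 was 0.15, and that of genes raised by OIR with anti-VEGFA at P17 was −0.18. Without 1 library the bispecific median for lowered genes ran from 0.15 to 0.35 (without its replicate 2) at P17 and from −0.02 (without its replicate 3) to 0.13 at P19.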

Other observations

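Genes and lists in this part follow the rule fixed before the data were examined, and the values on single libraries in the last paragraph were chosen after the results were seen. Among the genes with the largest folds of OIR at P17, Serpine3, a serpin, rose 66.9-fold (242 ± 129 against 3.62 ± 1.34 CPM, n = 4 each, adjusted p = 8.5e-05), and Serpina3n, an acute-phase serpin of reactive astrocytes, 11.1-fold (14.3 ± 7.81 against 1.31 ± 0.851 CPM, adjusted p = 0.0019). Both kept their calls in every setting run for named genes and without any library. Mmp12, the macrophage metalloelastase (17.1-fold, adjusted p = 0.045), and Ptgfr, the prostaglandin F receptor (15.5-fold, adjusted p = 0.036), were called but lost their calls with pigment epithelium and lens covariates. Mmp12 also lost it with RLE factors and with the mitochondrial share (adjusted p up to 0.22 over these settings), and Ptgfr with a replicate block. Both lost the call without control replicates 1 or 3 or IgG replicates 2 or 3. Mmp12 lost it also without control replicate 4 or IgG replicate 4, and Ptgfr without control replicate 2. In these fits without 1 library the adjusted p went up to 0.17 for Mmp12 and 0.15 for Ptgfr. At P19 Cd300c2, a receptor of myeloid cells, rose 10.8-fold (6.36 ± 0.524 against 0.574 ± 0.453 CPM, adjusted p = 0.0042), and C3ar1, the receptor for complement C3a, 5.37-fold (adjusted p = 0.0038), and both kept their calls in every setting and without any library. Irf5, an interferon regulatory factor (6.06-fold, adjusted p = 0.023), lost its call with Y-linked counts as a covariate, with limma-trend, and without control replicates 1, 2 or 3 or IgG replicate 1 (adjusted p up to 0.2). Cox4i2, a cytochrome c oxidase subunit of pericytes, rose 2-fold (58.5 ± 11.3 against 29.3 ± 4.77 CPM, adjusted p = 0.0054) and Cebpd, an acute-phase transcription factor, 3.35-fold (adjusted p = 0.0073), and both lost their calls without IgG replicate 1 (adjusted p = 0.056 and adjusted p = 0.051).

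Several lists that bear on vessels were not called in OIR. Blood-retina barrier genes had medians of −0.14 at P17 and −0.02 at P19 (log2, 15 genes, adjusted p = 0.79 and adjusted p = 0.38), Norrin and Wnt signalling −0.04 and −0.09 (12 genes, adjusted p = 0.8 and adjusted p = 0.89), and VEGF and angiopoietin ligands and receptors 0.13 and 0.09 (1 of 17 called at each age, adjusted p = 0.11 and adjusted p = 0.46). Matrix genes had medians of 0.45 and 0.33 with 0 of 25 called (adjusted p = 0.0076 and adjusted p = 0.015, but adjusted p = 0.16 and adjusted p = 0.19 with an estimated correlation), or 0.25 without IgG replicate 1 at P17 and 0.16 without IgG replicate 4 at P19 (adjusted p = 0.14). Neutrophil genes (4 measured, −1.58 and −0.06, adjusted p = 0.73 and adjusted p = 0.89) and lymphocyte genes (6 measured, −0.21 and 0.56, adjusted p = 0.55 and adjusted p = 0.95) were not called. Astrocyte genes were higher at P17 in 6 of 6 cases (median 0.55, 1 called, adjusted p = 0.0013, but adjusted p = 0.079 with an estimated correlation) and not called at P19 (0.4, adjusted p = 0.24). Müller glia identity genes had a median of 0.1 at P17 (adjusted p = 0.14) and 0.5 at P19 (11 of 14 positive, 0 called, adjusted p = 0.001, but adjusted p = 0.37 with an estimated correlation). The unfolded protein and integrated stress response had a median of 0.27 at P17 with Atf3 called (3.42-fold, 1 of 15, but not without control replicates 2 or 4 or IgG replicate 2; list adjusted p = 0.013, but adjusted p = 0.28 with an estimated correlation, and adjusted p = 0.057 without IgG replicate 2) and 0.06 at P19 (adjusted p = 0.38). Cholesterol synthesis (−0.15 and −0.16, 19 genes, adjusted p = 0.47 and adjusted p = 0.17) and lens genes (0.84 and −0.25, 9 genes, adjusted p = 0.99 and adjusted p = 0.31) were not called. Horizontal cell genes had a median of −0.02 at P17 (adjusted p = 0.67) and oxidative phosphorylation 0.33 at P19 (18 of 21 positive, 0 called, 9 adjusted over the list alone, adjusted p = 5.2e-06, but adjusted p = 0.38 with an estimated correlation).

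With age in control retinas further lists moved with the preset correlation and lost their calls with an estimated one. Ganglion cell genes had a median log2 change of 0.4 (11 of 13 positive, adjusted p = 9.5e-05, but adjusted p = 0.38 with an estimated correlation) and bipolar cell genes −0.27 (15 of 16 negative, adjusted p = 9.5e-05, but adjusted p = 0.38 with an estimated correlation). Pigment epithelium genes had 0.96 (adjusted p = 9e-06, but adjusted p = 0.38 with an estimated correlation) and red blood cell genes 1.29 (6 of 6 positive, adjusted p = 1.2e-05, but adjusted p = 0.13 with an estimated correlation).

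Some values concern single libraries. Bispecific P17 replicate 2 held muscle RNA (Acta1 125 CPM, Ckm 58.4 CPM, Atp2a1 78.9 CPM). Anti-VEGFA P19 replicate 3 held both Xist (104 CPM) and Y-linked counts (219 CPM summed over 4 genes).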
